A study of Homo sapiens with 6 samples.

How the data were processed

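RNA was sequenced from 6 cultures of 2 human ovarian cancer cell lines, A2780 and OVCAR3, with 1 library per culture. Per the labels, poly-A RNA was selected, libraries were made with a stranded kit, and single-end reads of 75 bases were generated on an Illumina NextSeq instrument. The deposited table gives 1 value per gene and library, in FPKM (fragments scaled by transcript length and by the number of mapped fragments) per the file headers; because 1.1% of the cells hold a word in place of a number, the authors' unit was recorded as other in the inventory of the files, and the values were used as FPKM. The submitters' processing notes name GRCh38, STAR 2.5.0 and RSEM 1.2.25 without saying what each made. The loci in the table are those of the earlier build GRCh37 (hg19), and its layout is that of a Cufflinks tracking table, so the notes and the table do not match and the program behind the values is not settled. Positions are given in GRCh37. The table's own name says that it was filtered, and the filter is not stated.

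The table held 25275 entries under 23607 distinct gene names. The 1304 entries on alternate haplotypes or unplaced contigs were left out; those with a number all stood at 0.001 FPKM, the lowest value in the table. Also left out were 274 entries marked as having too little data in every library, 2 marked as failed in some libraries, and 28 whose gene name had been turned into a calendar date. The 306 names with several loci on the main chromosomes were left out as well, since their values could not be assigned to 1 locus, and 23145 genes were kept.

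Read counts per library were not used here. Depth was judged from the steps between the lowest FPKM values of the same genes in different libraries: relative to A2780 scrambled shRNA at 1, it was 0.879 in A2780-shCOL11A1, 0.747 in A2780CIS, 1.58 in A2780-COL11A1, 1.14 in OVCAR3-GFP and 0.501 in OVCAR3-COL11A1. These ratios are estimates, no interval could be derived from them, and absolute depth is unknown.

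Libraries were grouped as the series describes: COL11A1-high (A2780CIS, A2780-COL11A1, OVCAR3-COL11A1) and COL11A1-low (A2780 scrambled shRNA, A2780-shCOL11A1, OVCAR3-GFP). The 3 libraries of a group are different constructs and lines, not repeats of 1 culture, so the spread within a group is a spread between constructs. Values were put on the scale log2(FPKM + 1), and 12841 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model with group and cell line, moderated variances with an intensity trend, two-sided). The Benjamini-Hochberg threshold was 5%. A model with a group by line interaction tested whether the difference varied between the lines. Gene lists with at least 5 tested members, 33 in all, were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data; fry was run beside them. The lists were written before the data were examined. The inhibitor of apoptosis, fatty acid beta-oxidation and NF-kB target lists were taken from themes of the group's own work and are not independent evidence.

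Each construct was also compared with a control of its line as 1 library against 1, with no test. A2780-COL11A1, A2780-shCOL11A1 and A2780CIS shared 1 control, A2780 scrambled shRNA. A2780 had no overexpression control, so A2780-COL11A1 also differs from its control in construct type. Genes at a ratio of at least 2-fold on the scale log2(FPKM + 1) were counted, and the median of each list was placed among the medians of 10000 random lists matched on mean expression. Fold changes of different pairs were compared across genes only for pairs sharing no library, since a shared control makes differences alike.

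Named genes were chosen by a rule fixed before the data were examined. For the group comparison these were 12 genes per direction among those past the threshold with no overlap between the groups within either line, filled, where fewer passed, by the smallest unadjusted p. For each pair they were the 8 highest and 8 lowest ratios with at least 5 FPKM in the higher library, and for both overexpression pairs together up to 10 per direction by the smaller of the ratios. Up to 4 members per list, 6 genes per line, COL11A1, BIRC2, BIRC3, XIAP, BIRC5 and CPT1A were added. Unnamed loci, pseudogenes and small RNAs were left out. Genes whose locus overlaps another gene in the table are named as such, since reads can be assigned to either.

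The test was run on simulated data with the design and gene variances of these libraries, 20 runs with 200 changed genes each. It recovered 11% of genes changed by a log2 difference of 1, 81.3% at 2 and 98.5% at 4, and 4.82% of unchanged genes had an unadjusted p under 0.05. The simulated genes varied independently of each other; there camera called 0 lists when nothing changed, and called a glycolysis list shifted by 1 in 20 of 20 runs, which does not show how often it calls lists whose genes vary together. In 60 runs with the random lists, 8.33% of unchanged lists lay outside the central 95% of random medians. These simulated values also varied independently, with the spread of 1 pair, and random lists hold unrelated genes. The share thus does not show how often lists whose genes vary together lie outside in the 1-against-1 comparisons.

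The alternatives tried were other pseudocounts, other filters on low values, quantile normalization and median scaling, no cell line term, no variance trend, leaving out each library, A2780 libraries only, overexpression libraries and their controls only, and A2780-shCOL11A1 as the control of A2780-COL11A1. Removing each library's trend on GC content or transcript length was added after the data were seen. The estimated correlation was planned beside the preset one in the list test, and was added to these alternatives after the data were seen. Python 3.11.15 and numpy 2.4.6 were used for the pairs, matplotlib 3.10.9 for the plots.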

Results

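The series asks which mRNAs differ between ovarian cancer cells with high and low COL11A1, the gene for the alpha 1 chain of type XI collagen. Expression was measured by RNA sequencing in 6 libraries, 3 per group. The COL11A1-low group held A2780 with a scrambled shRNA (replicate 1), A2780 with an shRNA against COL11A1 (A2780-shCOL11A1, replicate 2) and OVCAR3 with GFP (OVCAR3-GFP, replicate 3). The COL11A1-high group held A2780CIS, per the labels a cisplatin-resistant derivative of A2780 with high endogenous COL11A1 (replicate 1), A2780 overexpressing COL11A1 (A2780-COL11A1, replicate 2) and OVCAR3 overexpressing COL11A1 (OVCAR3-COL11A1, replicate 3). Each construct was sequenced once, so the replicates are different constructs and single values carry no error. FPKM values summed to between 426102 in OVCAR3-COL11A1 and 528744 in A2780CIS, and the estimated depth of OVCAR3-COL11A1 was 0.501 of that of A2780 scrambled shRNA, the lowest of the 6. Across genes, log2(FPKM + 1) of A2780 scrambled shRNA correlated with Pearson's r of 0.995 with A2780-shCOL11A1, 0.988 with A2780-COL11A1 and 0.940 with A2780CIS; r was 0.973 between the OVCAR3 libraries. Genes are not independent replicates in these correlations.

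COL11A1 (chromosome 1, 103342022 to 103574052, GRCh37) was higher in each COL11A1-high library than in the control of its own line. A2780CIS had 297 FPKM against 4.23 in A2780 scrambled shRNA, a ratio of 70.3. A2780-COL11A1 had 8.17 FPKM, 1.93 times the scrambled control. OVCAR3-COL11A1 had 1.67 FPKM against 0.0258 in OVCAR3-GFP, a ratio of 65.0 that rests on a control value near 0 (a difference of 1.38 in log2(FPKM + 1), against 5.83 in A2780CIS), and A2780-shCOL11A1 had 0.670 FPKM, 0.158 of the scrambled control. The groups were not separated by COL11A1 across lines, since A2780 scrambled shRNA, in the low group, lay above OVCAR3-COL11A1, in the high group. The log2 difference between the groups was 3.22 ± 1.39 (SE, limma), with an adjusted p of 0.731, and 1.53 without A2780CIS.

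**Figure D1:**
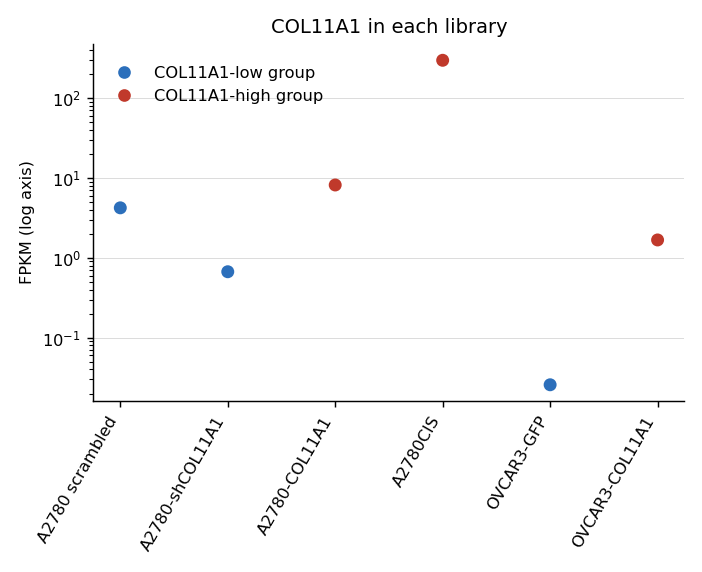
COL11A1 in FPKM on a log axis, 1 point per library, coloured by group. A2780CIS stands highest at 297 FPKM, and OVCAR3-COL11A1 at 1.67 lies below A2780 scrambled shRNA at 4.23.

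The comparison of the COL11A1-high with the COL11A1-low libraries over both lines asks which genes go with the COL11A1 group whatever the line. In A2780 both low libraries carry an shRNA and neither high library is labelled with one. There the groups differ in construct type as well as in COL11A1, and these cannot be told apart. MAT2A, which makes the methyl donor S-adenosylmethionine (chromosome 2, 85766100 to 85772403), was lower in every COL11A1-high library than in the low libraries of its line. It was at 124 FPKM in A2780CIS and 130.4 in A2780-COL11A1 against 368 and 401 in the low A2780 libraries. In OVCAR3-COL11A1 it was at 34.2 against 79.0 in OVCAR3-GFP. The log2 difference between the groups was -1.45 ± 0.17 (SE). NR1D2, a nuclear receptor of the circadian clock (chromosome 3, 23986750 to 24022109), was higher, at 12.3 and 11 FPKM against 4.26 and 4.91 in A2780 and at 153 against 67.2 in OVCAR3 (1.18 ± 0.17). TXNIP, an arrestin-family protein that restrains glucose uptake (chromosome 1, 145438461 to 145442628), was at 68.0 and 46.3 FPKM against 16.7 and 18.1 in A2780 and at 168 against 89.3 in OVCAR3 (1.39 ± 0.24). Its relative ARRDC4 differed by 1.34 ± 0.26. No gene passed the Benjamini-Hochberg threshold of 5% in limma, where the smallest adjusted p was 0.731, so these genes are given as values.

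HEXIM1, an inhibitor of the elongation factor P-TEFb, differed by -1.2 ± 0.19, the transporter gene MFSD5 by -1.27 ± 0.18 and TST, a mitochondrial sulfurtransferase, by -1.24 ± 0.18. The rule for named genes also took, among genes lower within both lines, PLEKHF1, EPHX1, GTDC2, RAB20, SCAND1, LZTS2, TUBB4B and HSPA1A. Among genes higher within both lines it also took HNRPLL (1.46 ± 0.24), DDB2, which recognizes DNA damage from ultraviolet light (0.87 ± 0.17), UPP1, RFK, FAM65A, TIPRL, MMADHC, ZNF638 and ACAD11. The loci of MAT2A, TST, EPHX1, LZTS2, TUBB4B and ACAD11 overlap other genes of the table, and HSPA1A is nearly identical to HSPA1B, so their values are less certain. At an unadjusted p under 0.05, 309 genes were higher and 523 lower, 6.48% of the 12841 tested; the total of 832 was 192 without A2780 scrambled shRNA, 193 without A2780-shCOL11A1, 1968 without A2780-COL11A1, 1261 without OVCAR3-GFP and 1254 without OVCAR3-COL11A1. Groups did not overlap within either line for 1301 higher and 1575 lower genes, 22.4% of those tested. Equally likely orders of the libraries would give 16.7%, but the A2780 libraries are not equally alike. Pearson's r was 0.995 between the low ones and 0.940 between A2780 scrambled shRNA and A2780CIS. The 22.4% is thus no measure of an excess over chance. Of 600 genes on the fixed lists, 0 passed when adjusted over those lists together (smallest adjusted p 0.467), and the interaction with line passed for 0 genes (limma; 1743 at an unadjusted p under 0.05).

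**Figure D2:**
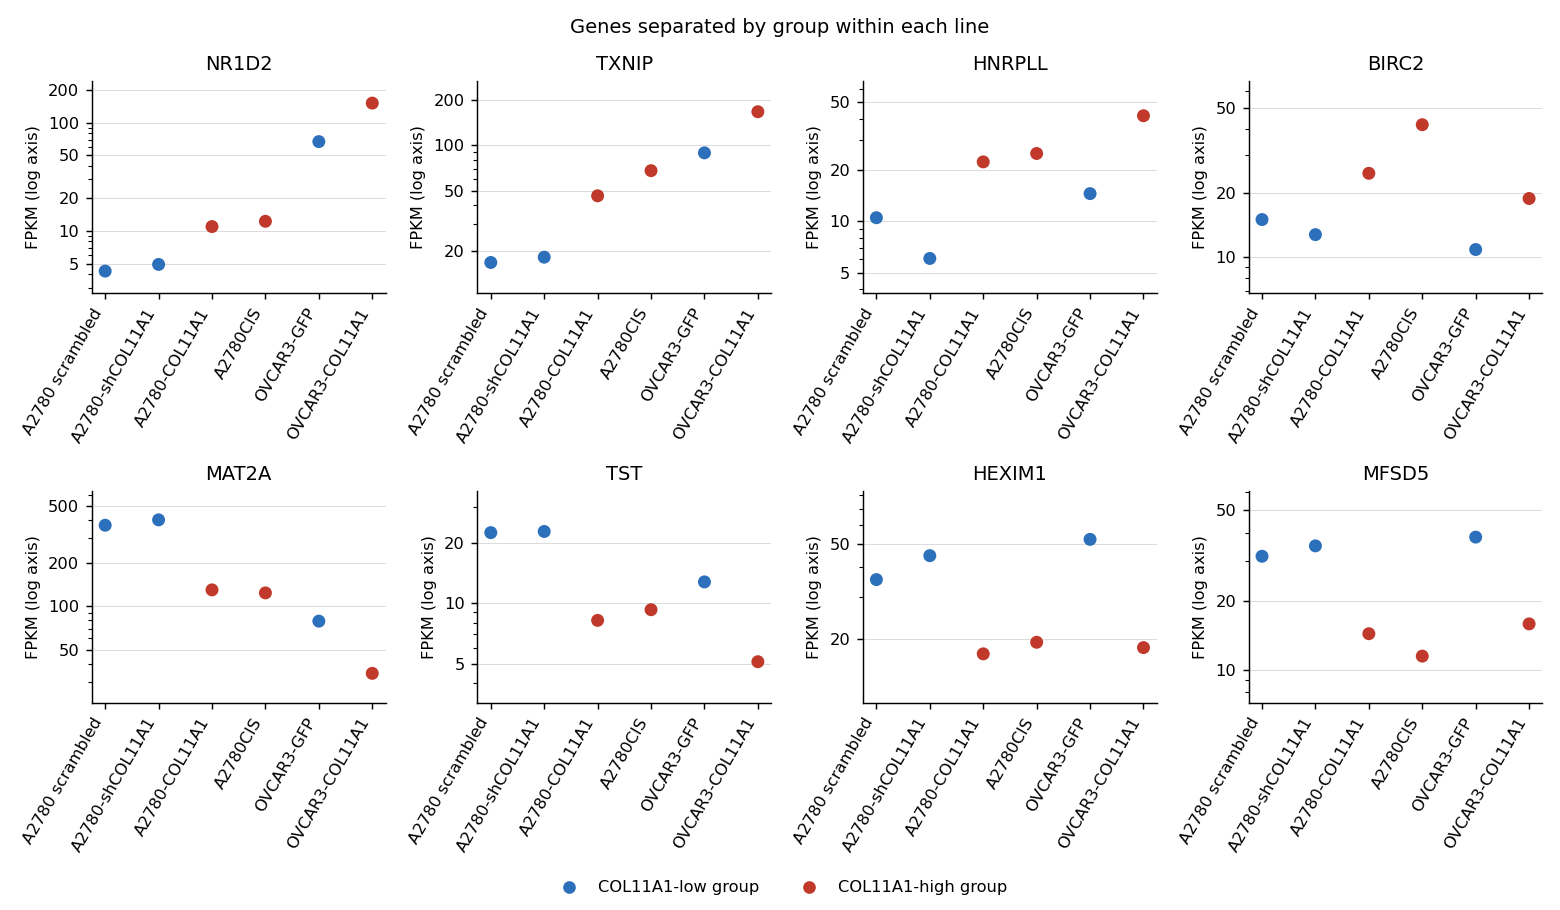
FPKM on a log axis of 8 genes, 1 panel per gene and 1 point per library, coloured by group. Within each line every COL11A1-high library lies on the same side of the low libraries, as for MAT2A with 34.2 FPKM in OVCAR3-COL11A1 against 79.0 in OVCAR3-GFP. Except for BIRC2, this separation was a condition for naming these genes, so it is no result of its own. No gene passed the threshold.

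NF-kB target genes were higher in the COL11A1-high group, with a median log2 difference of 0.93 and 16 of 18 tested members positive. RELB, an NF-kB subunit, differed by 1.48 ± 0.37, the feedback inhibitor NFKBIA by 1.19 ± 0.37 and the chemokine gene IL8 by 1.32 ± 0.63. The list passed with the preset correlation (camera, adjusted p = 1.85e-06) and did not with an estimated one (adjusted p = 0.650 with an estimated correlation). The mean difference of the list was 0.84 in the full comparison and 0.30 without either OVCAR3 library, where 7 of the 18 members were under 1 FPKM in every A2780 library. The list was taken from the study's own themes and is not independent evidence; adjusted over the list alone, 0 members passed (smallest adjusted p 0.0659; limma, 6 at an unadjusted p under 0.05).

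Immediate early genes, which respond quickly to growth factor signals, were higher in 22 of 25 members (median 0.64, adjusted p = 3.86e-06; adjusted p = 0.650 with an estimated correlation). DUSP6 and SPRY4, feedback inhibitors of ERK signalling, differed by 1.95 ± 0.70 and 1.84 ± 0.52. The mean of the list was 0.68, 0.42 without A2780CIS and 0.60 without A2780 scrambled shRNA. The list was also higher in A2780-shCOL11A1, of the low group, than in A2780 scrambled shRNA (median 0.18).

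In the inhibitor of apoptosis family 4 of 5 tested members were positive, with a median of 0.15 (adjusted p = 0.0499; 0.650 as adjusted p with an estimated correlation). BIRC2 (chromosome 11, 102217912 to 102249401), which encodes the ubiquitin ligase cIAP1, had 41.8, 24.7 and 18.9 FPKM in the high libraries against 15.0, 12.8 and 10.9 in the low ones (1.02 ± 0.26). XIAP differed by 0.41 ± 0.18 and BIRC5 by 0.15 ± 0.19. BIRC3 lay below the minimum for testing, at 2.05 FPKM in OVCAR3-COL11A1 and 0.134 in OVCAR3-GFP. Adjusted over the list alone, 1 gene, BIRC2, passed (adjusted p 0.0388), and over all genes tested it did not; the study chose this list too, so it is not independent evidence. The list's call was kept in 4 of 18 alternatives, and ended without either OVCAR3 library (mean 0.29), without A2780 scrambled shRNA (0.34) and without A2780-COL11A1 (0.36).

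Of 26 tested genes of fatty acid beta-oxidation, 21 were positive, with a median of 0.16 (adjusted p = 0.0190; adjusted p = 0.650 with an estimated correlation). DECR1, which handles unsaturated fatty acids in mitochondria, differed by 1.05 ± 0.38, while CPT1A, the gate of fatty acid entry into mitochondria, differed by 0.39 ± 0.54, with 25.7 FPKM in A2780CIS against 7.36 in the scrambled control and 36.7 in OVCAR3-COL11A1 against 60.3 in OVCAR3-GFP. CPT1A turned to -0.24 without A2780CIS. The list's call ended without A2780CIS (mean 0.15 against 0.25), without A2780-COL11A1 (0.26) and without A2780-shCOL11A1 (0.16); without either OVCAR3 library the mean was 0.39 and the call was kept. It ended with overexpression libraries and their controls only. This list was also the study's own choice and is not independent evidence; adjusted over the list alone, 0 members passed (smallest adjusted p 0.487; limma, 1 at an unadjusted p under 0.05).

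Glycolysis genes were lower in the COL11A1-high group, with 2 of 22 positive, a median of -0.51 and an adjusted p of 6.67e-05 (adjusted p = 0.650 with an estimated correlation). PFKFB4, which sets the level of a glycolytic activator, differed by -1.63 ± 0.42 and the neuronal enolase ENO2 by -2.12 ± 1.2. The hypoxia response list followed with a median of -0.25 and 6 of 20 positive (adjusted p = 0.0499; adjusted p = 0.650 with an estimated correlation). CA9, a carbonic anhydrase, differed by -1.50 ± 0.57 and the glucose transporter SLC2A1 by -0.86 ± 0.27. A2780 scrambled shRNA, in the low group, was above the other A2780 libraries in the median of both lists; without it the means were -0.43 for glycolysis and -0.12 for hypoxia. The hypoxia call ended without that library and without A2780CIS (-0.21), A2780-COL11A1 (-0.24) or either OVCAR3 library (-0.45). It was kept in 6 of 19 alternatives, and ended also with a pseudocount of 0.1, a mean of at least 5 FPKM, no cell line term, no variance trend, or the GC or length trend removed. With the GC trend removed the hypoxia median was -0.27, about as large as in the main fit.

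Interferon response genes (4 of 23 positive, median -0.62, adjusted p = 0.0105), antigen presentation genes (1 of 15, median -0.63, adjusted p = 0.0190) and histone genes (0 of 10, median -0.64, adjusted p = 0.0188) were lower in the high group; none passed with an estimated correlation (adjusted p = 0.650 with an estimated correlation for each). BST2, an antiviral membrane protein, differed by -3.20 ± 1.95, HLA-B by -1.05 ± 0.94 and HIST1H2BD by -1.39 ± 0.37. These calls ended without A2780CIS, where the means were -0.14, -0.04 and -0.09, and that of antigen presentation also ended without either OVCAR3 library (mean -0.95). All 3 ended with overexpression libraries and their controls only. Without A2780-COL11A1 the means were -0.85, -1.05 and -1.01. Canonical histone mRNAs lack a poly-A tail, so their values also depend on the selection of RNA.

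Epithelial markers were lower, with 6 of 21 positive and a median of -0.32 (adjusted p = 0.0302), and so were NRF2 and glutathione genes (3 of 19, -0.41, adjusted p = 0.0251) and ovarian lineage markers (1 of 10, -0.23, adjusted p = 0.0302), all with an adjusted p = 0.650 with an estimated correlation. The tight junction gene CLDN4 differed by -1.39 ± 0.95, the heme oxygenase HMOX1 by -0.92 ± 0.76, the folate receptor FOLR1 by -1.70 ± 0.51 and the adhesion molecule BCAM by -1.65 ± 0.35. Without either OVCAR3 library the means of the epithelial and NRF2 lists were 0.00127 and 0.00145 and that of the ovarian lineage list -0.34, and all 3 calls ended, but 14 of 21 epithelial and 6 of 10 ovarian lineage markers were under 1 FPKM in every A2780 library; the NRF2 call also ended without A2780CIS (mean -0.33), and the mean was -0.63 without A2780-COL11A1. The epithelial call was kept in 11 of 19 alternatives and the ovarian lineage call in 10 of 19; both ended with a mean of at least 5 FPKM, no cell line term or the GC trend removed, the epithelial call also with quantile normalization, and the ovarian lineage call also with a pseudocount of 0.1 or no filter. With the GC trend removed the epithelial median was -0.19 and the ovarian lineage median -0.14. After quantile normalization the epithelial median was -0.30. The NRF2 call was kept in 13 of 19 and ended with no filter. Adjusted over the list alone, BCAM passed among ovarian lineage markers and HSPA1A and HSPA1B, near-identical copies, passed among 13 heat shock genes.

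In total 12 of 33 lists passed with the preset correlation, 4 higher and 8 lower, and 0 passed with the estimated correlation or with fry (camera and fry; 0.650 was the smallest adjusted p with an estimated correlation). Among the lists that did not pass were fibrillar and network collagens (median 0.12), matrix glycoproteins and remodelling (0.10), collagen receptors and integrins (-0.23), TGF-beta response (0.33), mesenchymal markers (0.57, with a mean of 0.05), platinum transport and detoxification (-0.16) and DNA repair (-0.11). Median, mean and test differed in sign for the BCL2 family (median -0.07, mean 0.04), p53 targets (median -0.03, mean 0.10), heat shock (median 0.03, mean -0.03) and oxidative phosphorylation (median -0.13, mean -0.03, test higher).

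A2780-COL11A1 against A2780 scrambled shRNA asks what added COL11A1 goes with in A2780. The control carries a scrambled shRNA and not an overexpression control, so construct type differs along with COL11A1 and cannot be told apart from it. Genes of cholesterol synthesis were higher, with a median of 0.50 and 17 of 19 members positive; HMGCS1, which feeds the mevalonate pathway, had 55.5 FPKM against 27.4. Immediate early genes had a median of 0.59, with ATF3 at 42.8 against 13.6 and FOS at 9.34 against 3.36. Glycolysis and hypoxia genes were lower, with medians of -0.53 and -0.51; PFKP had 12.8 FPKM against 38.9 and CA9 1.05 against 7.69. The chemokine receptor CXCR4 was at 2.08 FPKM against 40.3 and S100A4, a calcium-binding protein of motile cells, at 47.3 against 239.

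The other genes with the lowest ratios were HES7, PLSCR3, DHRS2, PLOD2 and FAM110D. Among the highest were HYPK, KHDC1L, OSTN (33.5 FPKM against 6.16), IL2RB (11.9 against 1.85), TGIF2-C20orf24 and PAX9 (14.0 against 2.80); HYPK, TGIF2-C20orf24 and PLSCR3 overlap other genes of the table. HYPK and TGIF2-C20orf24 were also higher in A2780-shCOL11A1 against the same control, at 14.2 FPKM against 3.07 and 6.48 against 0.794. On the scale log2(FPKM + 1), 109 genes were at least 2-fold higher and 245 at least 2-fold lower. Of 33 lists, 9 medians lay above and 4 below the central 95% of random lists. The other medians outside it were those of the inhibitor of apoptosis family (0.36), NRF2 and glutathione genes (0.31), oxidative phosphorylation (0.28), fatty acid synthesis (0.22), NF-kB targets (0.19), Hippo-YAP response (0.15), fatty acid beta-oxidation (0.14), collagen receptors and integrins (-0.31) and fibroblast markers (-0.52). Median scaling moved fatty acid beta-oxidation to 0.25 and Hippo-YAP response to 0.26, and quantile normalization moved oxidative phosphorylation to 0.17 and Hippo-YAP response to 0.25. With 1 library per arm no difference was tested, and with A2780-shCOL11A1 as the control 226 genes were higher.

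OVCAR3-COL11A1 against OVCAR3-GFP asks the same in OVCAR3. NF-kB targets were higher, with a median of 1.97, 17 of 18 members positive and 14 at least 2-fold higher. TNFAIP3, a feedback inhibitor of NF-kB, had 88.3 FPKM against 4.64, and the chemokine genes CXCL3, IL8 and CXCL1 had 50.4 against 2.46, 49.4 against 3.94 and 222 against 27.3. Genes of cholesterol synthesis were lower in 19 of 19 members, with a median of -1.41; HMGCS1 had 42.3 FPKM against 241 and the squalene epoxidase SQLE 38.2 against 209. Genes of fatty acid synthesis (median -1.04) and NRF2 and glutathione genes (-1.04) were also lower, with FASN at 43.4 FPKM against 129 and NQO1 at 9.15 against 33.8. Epithelial markers had a median of -0.82, with CLDN4 at 8.84 FPKM against 228 and CLDN3 at 3.69 against 34.3.

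Hippo-YAP response genes had a median of 0.81, with AJUBA at 62.4 FPKM against 14.6 and CYR61 at 135 against 38.4, and fibrillar and network collagens one of 0.56, with COL5A2 at 36.1 against 10.5. Glycolysis genes (-0.72), ovarian lineage markers (-0.67), platinum transport and detoxification (-0.48), Notch response (-0.42), collagen folding and secretion (-0.38) and interferon response (-0.38) lay below the random lists. Ribosomal proteins had a median of -0.72 with 0 of 32 members positive, and -0.21 after quantile normalization; with the GC trend removed the median was -0.41 for ovarian lineage markers and -0.22 for Notch response. The other highest genes were SAMD11, ZFP30 (113 FPKM against 11.3), ZNF569 (52.7 against 5.25), SNAPC1 and PTX3, and among the other lowest were THRSP, SNURF, HMOX1 (0.492 against 11), TMEM100 and THEMIS2. TNFAIP3, SAMD11, PTX3, THRSP and SNURF overlap other genes of the table, and SNURF was low where SNRPN was not, so it is uncertain. In this pair 872 genes were at least 2-fold higher and 537 lower, and 3 list medians lay above and 11 below the central 95% of random lists. OVCAR3-COL11A1 had the lowest depth of the 6 libraries, and across genes its ratio to OVCAR3-GFP was lower at higher GC content (Spearman's rho -0.402).

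**Figure D3:**
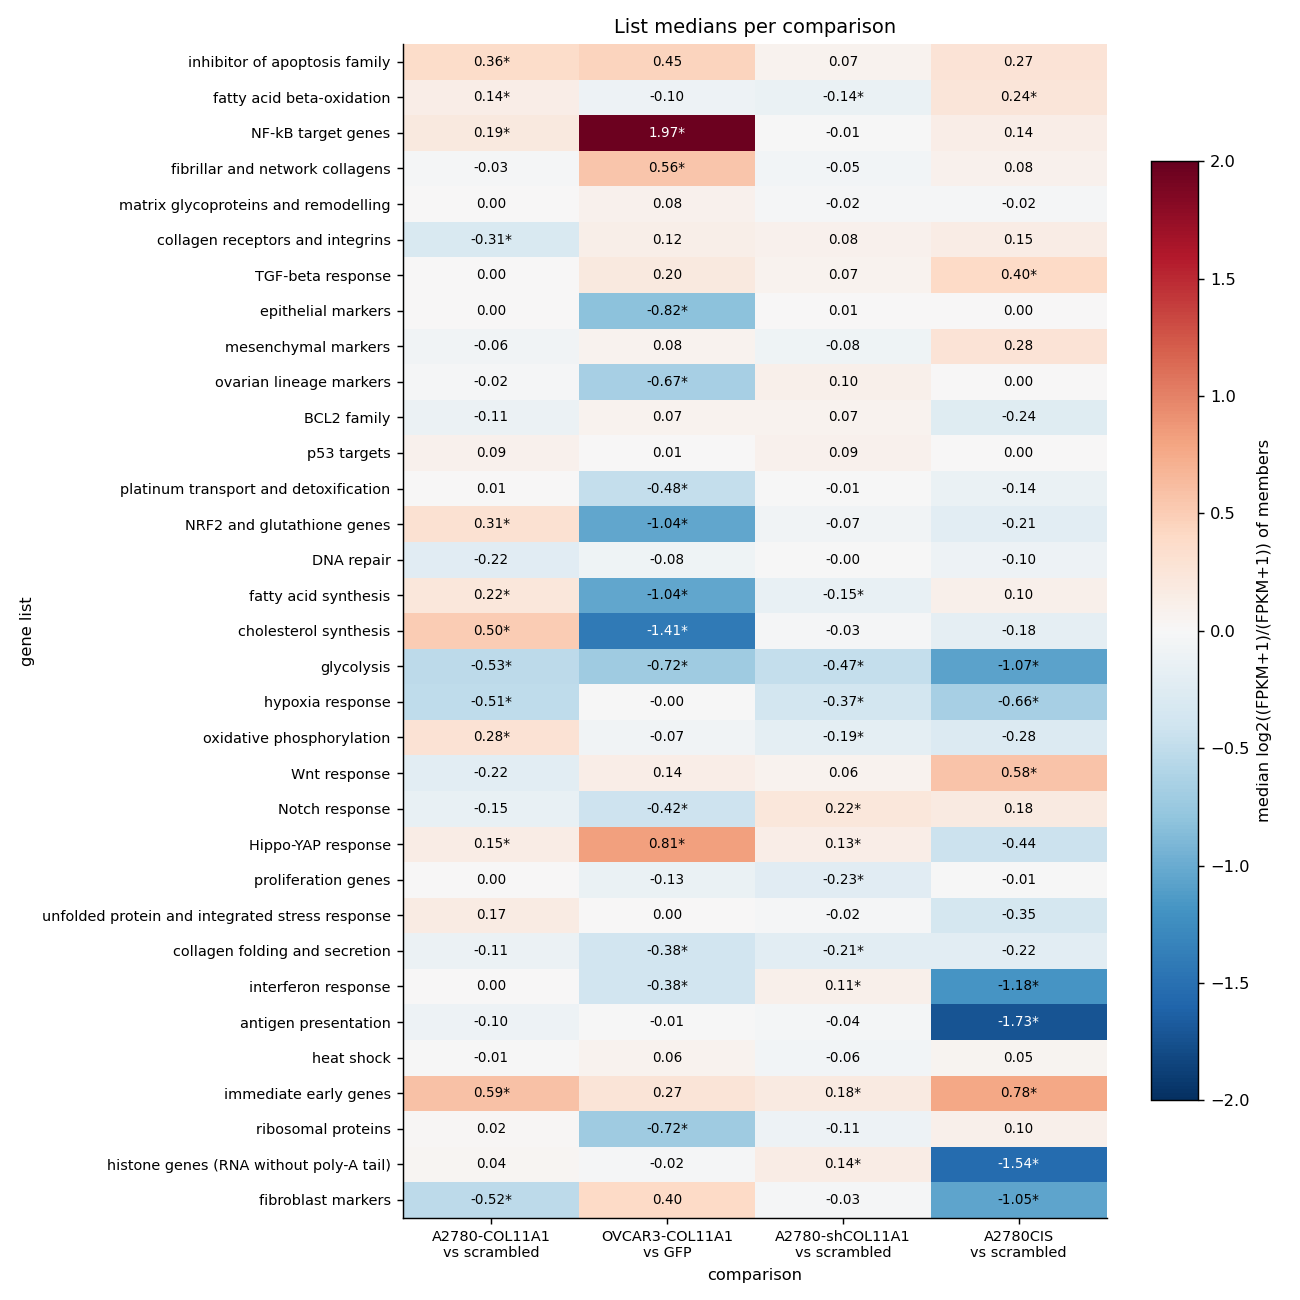
Median log2((FPKM+1)/(FPKM+1)) of each gene list (down the side) in each comparison of 1 library with its control (across); the colour scale runs from -2 to 2 and an asterisk marks a median outside the central 95% of random lists. NF-kB targets reach 1.97 and cholesterol synthesis -1.41 in OVCAR3-COL11A1, and antigen presentation -1.73 in A2780CIS.

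Taking the overexpression pairs together, NFKBIA was higher in both, at 56.6 FPKM against 22.5 in A2780 and 265 against 65.7 in OVCAR3. ATF3, a stress-response transcription factor, was at 34.4 FPKM against 13.8 in OVCAR3, and PPP1R15A, which restores translation after stress, at 76.8 against 29.4 in A2780 and 121 against 53.6 in OVCAR3. CXCL10, FN1, IL32, CYR61, NR1D2, RASSF9 and LNP1 were also higher in both. Among those lower in both were ADORA1, PLEKHF1, MAT2A, TST, MEOX1, NME3, HDHD3, TMCC3 and SLC16A3.

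Few genes moved alike in the overexpression pairs. Across 12841 genes Pearson's r of the log2 ratios was -0.0400 (Spearman's rho -0.00914); 15 genes were at least 2-fold higher in both where independence gives 7.40, 14 lower in both where it gives 10.2, 16 higher in A2780 and lower in OVCAR3 where it gives 4.56, and 15 lower in A2780 and higher in OVCAR3 where it gives 16.6. OVCAR3-COL11A1 against OVCAR3-GFP had r of 0.0394 (rho 0.0640) with A2780CIS and 0.137 (rho 0.209) with A2780-shCOL11A1, each against scrambled. A2780-COL11A1 against scrambled and A2780CIS against A2780-shCOL11A1 had r of 0.223 (rho 0.268), with 26 genes higher in both where independence gives 9.60 116 lower in both where it gives 25.2, and 21 and 11 in opposite directions where it gives 11.2 and 21.6. These were the 4 relations computed, all across genes, which are not independent replicates.

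A2780-shCOL11A1 against A2780 scrambled shRNA asks what loss of COL11A1 goes with. Proliferation genes were lower in 27 of 30 members, with a median of -0.23; RRM2, which supplies DNA precursors, had 15.5 FPKM against 28.8 and the cell cycle factor E2F1 8.38 against 13.8. Glycolysis (median -0.47) and hypoxia (-0.37) genes were lower as well, with PGK1 at 157 FPKM against 281 and BNIP3 at 80.5 against 152. Immediate early genes had a median of 0.18, with EGR1 at 27.1 FPKM against 13.9. Differences were small, with 23 genes at least 2-fold higher and 25 lower.

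The highest ratios were those of EEF1E1-MUTED, TGIF2-C20orf24, HYPK, GNG8, RNF5, HIST3H2BB, HTR2B and EGR1, and the lowest those of BLOC1S5, H3F3A, REEP4, P2RX3, RAB11FIP1, SLX1A, WDR54 and FAM162A (45.4 FPKM against 93.9). EEF1E1-MUTED was at 5.94 FPKM against 0.00374 while the overlapping BLOC1S5 was at 0.00414 against 7.75, and H3F3A and SLX1A have near-identical copies, so these values are uncertain. Other list medians outside the central 95% of random lists were those of Notch response (0.22), histone genes (0.14), Hippo-YAP response (0.13), interferon response (0.11), fatty acid beta-oxidation (-0.14), fatty acid synthesis (-0.15, and -0.09 after quantile normalization), oxidative phosphorylation (-0.19) and collagen folding and secretion (-0.21). Of 33 lists, 5 lay above and 7 below; no difference was tested.

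A2780CIS against A2780 scrambled shRNA compares a culture labelled as a cisplatin-resistant derivative of A2780 with A2780 that carries a control shRNA. The matrix metalloproteinase genes MMP1 and MMP3 were at 1109.5 FPKM against 2.37 and at 1715 against 4.63, while the list of matrix glycoproteins and remodelling that holds them had a median of -0.02, inside the central 95% of random lists. BST2 was at 0.497 FPKM against 409, and TWIST1, a mesenchymal transcription factor, at 0.751 against 162. Antigen presentation genes had a median of -1.73 with 10 of 15 at least 2-fold lower; HLA-B was at 59.5 FPKM against 717 and the peptide transporter TAP1 at 7.58 against 74.6. Immediate early genes had a median of 0.78, with DUSP6 at 382 FPKM against 33.1 and SPRY4 at 126 against 15.3.

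Interferon response (-1.18), histone (-1.54), glycolysis (-1.07), fibroblast marker (-1.05) and hypoxia response (-0.66) medians also lay below the random lists, with ENO2 at 0.413 FPKM against 53.4 and PDGFRA at 1.42 against 66.1. Wnt response (0.58), TGF-beta response (0.40) and fatty acid beta-oxidation (0.24) lay above, with TNFRSF19 at 165 FPKM against 0.223, ID1 at 36.9 against 4.96 and ACSL1, which activates fatty acids, at 21.7 against 4.29. The other highest genes were KHDRBS3, TDO2, GNAI1, COL12A1 and MMP12, and the other lowest MEST, MAB21L1, RGS1, SHOX2, DLX5 and RBPMS; MMP1, MMP3, MEST, MAB21L1 and RBPMS overlap other genes of the table. In this pair 1083 genes were at least 2-fold higher and 1290 lower, the most of the 4 pairs. Of 33 lists, 4 medians lay above and 6 below the central 95% of random lists. Per the labels A2780CIS differs from the control in resistance as well as in COL11A1, and no difference was tested.

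**Figure D4:**
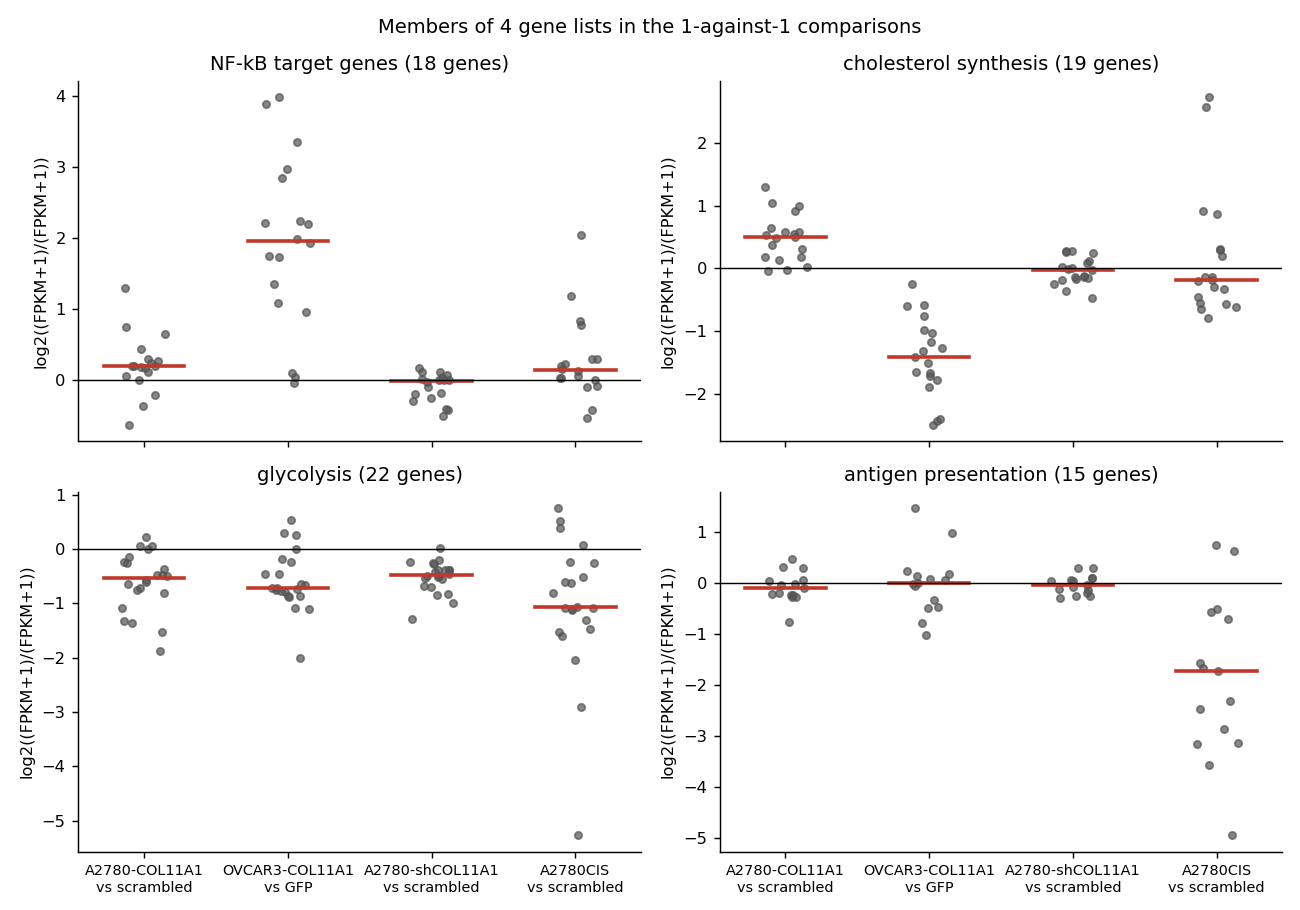
Each point is 1 gene of a list, placed by log2((FPKM+1)/(FPKM+1)) in each comparison of 1 library with its control; red bars are medians. NF-kB targets have a median of 1.97 in OVCAR3-COL11A1, cholesterol synthesis 0.50 in A2780-COL11A1 and -1.41 in OVCAR3-COL11A1, and the glycolysis median is below 0 in each of the 4 comparisons.

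The lines differed far more than the groups. OVCAR3 was higher in 2522 genes and A2780 in 3288, together 5810 of 12841 (limma, Benjamini-Hochberg 5%). Those higher in OVCAR3 numbered 1629 without A2780 scrambled shRNA and 1433 without OVCAR3-COL11A1. Those higher in A2780 numbered 1835 without A2780 scrambled shRNA, 2070 without A2780-shCOL11A1, 1877 without OVCAR3-GFP and 1748 without OVCAR3-COL11A1. The highest in OVCAR3 were WFDC2, which encodes the ovarian cancer marker HE4, SPINT2, SLPI, the keratins KRT8 and KRT7, and C19orf33; KRT7 had 393 and 429.6 FPKM in OVCAR3 and 0.001, the lowest value in the table, in each A2780 library. Among the highest in A2780 were HGF, SERPINF1, the mesenchymal filament gene VIM, FKBP10 and CCND2; HGF had 378 to 668 FPKM in A2780 and 0.0231 and 0.127 in OVCAR3.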

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

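In this part, the tests with A2780 libraries only for the NF-kB list, the counts of members under 1 FPKM, and the tests of added foreign RNA and of another cell line for A2780CIS, were chosen after the results were seen.

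In the interaction test 9 of 33 lists differed between OVCAR3 and A2780 with the preset correlation, and 0 with an estimated correlation, where adjusted p ranged from 0.582 to 0.751. The mean log2 difference, OVCAR3 minus A2780, was 1.62 for NF-kB targets (0.30 in A2780, 1.92 in OVCAR3; adjusted p = 3.11e-07). It was -1.75 for cholesterol synthesis (0.34 and -1.41; adjusted p = 8.68e-10). It was -1.07 for fatty acid synthesis (0.09 and -0.99), -1.12 for NRF2 and glutathione genes (0.00145 and -1.12) and -1.07 for epithelial markers (0.00127 and -1.07). Ribosomal proteins differed by -0.84 (0.13 and -0.70), Hippo-YAP response by 1.17 (-0.23 and 0.94), fatty acid beta-oxidation by -0.42 (0.39 and -0.03) and ovarian lineage markers by -0.34 (-0.34 and -0.68). Each OVCAR3 value rests on 1 library per arm, so the spread in this test is that of the A2780 libraries alone, which are different constructs, and is assumed to hold for OVCAR3. Of the tested members, 7 of 18 NF-kB targets were under 1 FPKM in every A2780 library, as were 14 of 21 epithelial and 6 of 10 ovarian lineage markers, whose fall could hardly show there on this scale. The OVCAR3 median of ribosomal proteins was -0.72, and -0.21 after quantile normalization.

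NF-kB targets were higher in the COL11A1-high group by a median of 0.93. Over the 17 members with a GC value the median was 0.86, and removing each library's GC trend left it at 0.94, 110% of that value. The 95% bootstrap interval was 93.3 to 122, over members and not over libraries. This argues against that trend as the cause. RNA from leukocytes is argued against by 0 of 16 leukocyte markers being 5 FPKM or more higher in OVCAR3-COL11A1 than in OVCAR3-GFP. With A2780 libraries only the median was 0.15, 16.4% of its value, with an interval of 8.95 to 51.3 that reaches past the bound set for it. The mean log2 difference of the list was 0.30 in A2780 and 1.92 in OVCAR3, so most of the group mean of 0.84 came from the OVCAR3 pair. Of the 18 members, 7 were under 1 FPKM in every A2780 library, the COL11A1-high ones included, which does not by itself hide a rise. Which OVCAR3 library was responsible stays open. An effect of COL11A1 itself stays open too, as untested with 1 OVCAR3 library per arm.

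A2780CIS stood apart from the other A2780 libraries. Of 48 genes at 10 FPKM or more in A2780CIS and under 0.5 in the other A2780 libraries, 12.5% were at least as high in OVCAR3-GFP, which argues against OVCAR3 RNA in that library. Of 6155 genes at 10 FPKM or more in the other 3 A2780 libraries, 78 were under 5% of the lowest of them in A2780CIS. This is more than foreign RNA added to RNA of otherwise unchanged A2780 would allow. Foreign RNA in a derivative that had itself lost these genes is not excluded. Of 198 genes typical of A2780 against OVCAR3, 32.8% were under 10% of the scrambled level, against 5 genes in A2780-COL11A1, and 92 kept 50% or more of it. The 32.8% has a Clopper-Pearson 95% interval of 26.3 to 39.8, which takes genes as independent. This share lies between the bounds set, so a different line under this label cannot be told apart from a far-diverged derivative. Divergence during selection for cisplatin resistance, which the labels name, stays open and was not tested.

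More genes were lower than higher in the COL11A1-high group at an unadjusted p under 0.05, 62.9% of 832. The share was 56.9% of 582 genes after the GC trend was removed (interval 52.7 to 60.9), 61.1% of 779 after the length trend was removed (57.6 to 64.5) and 55.9% of 790 after median scaling (52.4 to 59.4). These intervals treat genes as independent, though genes of the same 6 libraries vary together, so they may be too narrow. The GC and length shares cover the 11889 genes with those values, not all 12841 tested. None of the shares lay beyond its bound by more than its interval, so GC content, transcript length and scaling may each contribute. They cannot be told apart from a difference between the groups. Across genes, log2 differences were lower at higher GC content (Spearman's rho -0.313).

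The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 0 genes past the threshold in limma (832 at an unadjusted p under 0.05), a count that every split reaches by definition, so it says nothing about chance; the highest of the others gave 1428. That split parts A2780 scrambled shRNA, A2780-shCOL11A1 and A2780-COL11A1 from the rest, which with the line term sets A2780CIS against the other A2780 libraries and points to a structure of the samples. At an unadjusted p under 0.05 the real split gave 832 genes, 3 splits with the real one gave as many, and the highest other gave 3490, again for A2780CIS against the other A2780 libraries; among splits with 1 OVCAR3 library per group, as in the real one, the highest other gave 937. For gene lists the real split gave 12, 4 splits with the real one gave as many, and the highest other gave 18.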

How the results depend on the processing

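The removal of GC or length trends was chosen after the data were seen. The estimated correlation was planned for the list test and later counted among the alternatives. The replicate numbers follow the order of the samples and the labels pair no libraries, so no paired fit was made. In limma 0 genes passed in the COL11A1-high against COL11A1-low comparison in every alternative, with 74 genes (no cell line term) to 1968 (without A2780-COL11A1) at an unadjusted p under 0.05. Of 28 named genes, 0 passed in any alternative and 2 changed sign: BIRC5 was -0.0247 and CPT1A -0.34 with overexpression libraries and their controls only, and CPT1A was -0.24 without COL11A1-high replicate 1 (-0.24 to 0.93 leaving out single libraries). COL11A1 ranged from 1.1 to 4.45. The glycolysis, immediate early and NF-kB lists kept their call in 18 of 19 alternatives, losing it with the estimated correlation, where 0 lists passed. Those 18 all used the preset correlation of 0.01, so they do not test that setting. The estimated correlations were 0.333, 0.191 and 0.528 for these lists in turn. Leaving out single libraries gave 8 to 17 lists. The inhibitor of apoptosis list had too few members at a mean of 5 FPKM for a value. Epithelial markers turned to 0.00127 and NRF2 and glutathione genes to 0.00145 with A2780 libraries only and without either OVCAR3 library, which leaves the same information; leaving out others they went as low as -0.48 and -0.63. Genes higher in OVCAR3 numbered 1670 at a mean of 5 FPKM, where fewer genes are tested, and 1433 to 3096 leaving out single libraries; those higher in A2780 numbered 1748 to 4250.

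Counts of 2-fold genes in single pairs followed the pseudocount by construction. For 0.1 and 5 they were 264 and 40 higher and 505 and 77 lower in A2780-COL11A1, 1372 and 319 higher and 898 and 210 lower in OVCAR3-COL11A1, and 86 and 6 higher and 119 and 8 lower in A2780-shCOL11A1. A2780CIS had 561 higher and 601 lower with 5. Genes alike in both overexpression pairs were 44 and 4 higher and 58 and 2 lower. At a mean of 5 FPKM, where fewer genes remain, the counts were 70 higher and 162 lower in A2780-COL11A1, 565 higher in OVCAR3-COL11A1, 6 higher and 13 lower in A2780-shCOL11A1, 622 higher in A2780CIS and 9 higher in both overexpression pairs. With no filter A2780-shCOL11A1 had 36 higher. With A2780-shCOL11A1 as control A2780-COL11A1 had 226 higher. With the GC trend removed A2780-shCOL11A1 had 11 higher, and 6 genes were lower in both overexpression pairs; the cause was not tested.

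In the settings named here, correlations of fold changes moved by more than their interval over genes. That interval treats genes as independent, so it may be too narrow, and it does not measure the spread between libraries. For the overexpression pairs r was -0.0625 with a pseudocount of 0.1, -0.0114 after quantile normalization and -0.0880 with the GC trend removed. For A2780CIS with OVCAR3-COL11A1 it was 0.0142 and 0.0646 with pseudocounts of 0.1 and 5 and 0.00373 with the GC trend removed. For A2780-shCOL11A1 with OVCAR3-COL11A1 it was 0.0815 and 0.179, then 0.167 at a mean of 5 FPKM, 0.119 after quantile normalization and 0.0892 with the GC trend removed. For A2780-COL11A1 with A2780CIS against A2780-shCOL11A1 it was 0.193 and 0.249. The cause was not tested. With 1 library per construct and unknown depth, low values carry no error estimate.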

Other observations

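The zinc finger values and the comparison of the other A2780 libraries with A2780 scrambled shRNA were chosen after the data were seen. So were the GC-removed version of the neighbour test and the list members in its regions.

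Of 423 genes whose symbols begin with ZNF, 117 were at least 2-fold higher in OVCAR3-COL11A1 than in OVCAR3-GFP and 0 lower, 27.7% higher against 6.08% of the other genes. In A2780-COL11A1 0 were at least 2-fold higher and 15 lower (3.55% lower against 1.85% of the other genes), in A2780-shCOL11A1 0 and 0, and in A2780CIS 11 and 20 (4.73% lower against 10.2%), each against A2780 scrambled shRNA. No difference was tested. Their median GC content was 46.0%, against 50.3% for the other genes, and the OVCAR3 ratio was lower at higher GC content (Spearman's rho -0.402). The A2780-COL11A1 and A2780CIS ratios were too (-0.204 and -0.139), yet there the ZNF medians lay below those of the other genes (-0.25 against -0.03, -0.11 against -0.06). In A2780-shCOL11A1 (-0.246) the ZNF median lay above (0.08 against 0). ZNF genes thus did not follow the GC trend in every pair, and GC content as a cause was not tested.

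Glycolysis and hypoxia genes were lower than A2780 scrambled shRNA in the other 3 A2780 libraries, whether COL11A1 was lowered or raised. Medians for glycolysis were -0.47 in A2780-shCOL11A1, -0.53 in A2780-COL11A1 and -1.07 in A2780CIS, and for hypoxia -0.37, -0.51 and -0.66. Immediate early genes went the other way, higher than A2780 scrambled shRNA in all 3, with medians of 0.18, 0.59 and 0.78. Within each list all 3 values share the scrambled library.

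Neighbouring genes moved together in A2780CIS against A2780 scrambled shRNA, which may reflect copy number. Of 12287 windows of 25 neighbouring genes, 5.05% had medians beyond an extreme percentile of shuffled gene orders that was fixed in advance, and 4.61% after the GC trend was removed. OVCAR3-COL11A1 against OVCAR3-GFP gave 5.05% and 1.42%, A2780-COL11A1 1.11% and 0.468%, and A2780-shCOL11A1 0.741% and 0.132%. Every one of these shares lay above what shuffled orders give beyond that percentile, also between libraries as alike as A2780-shCOL11A1 and A2780 scrambled shRNA. Such windows alone thus do not single out copy number. In A2780CIS the regions included chromosome 8 from 74202873 to 99954799 (73 genes, median 0.71) and chromosome 1 from 85018803 to 109181949 (87 genes, -0.67), which holds COL11A1, itself 70.3 times higher. They also included 2 on chromosome 6: from 24357130 to 28057340 (53 genes, -0.62), with 8 of the 10 tested histone genes, and from 31626074 to 33257304 (49 genes, -0.59), with 6 of the 15 tested antigen presentation genes. Without those list members the medians were -0.49 and -0.49. Windows were not tested with clusters of related genes left out, so copy number is a hypothesis that DNA data, not analysed here, would have to test.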
